A study of Homo sapiens with 12 samples.

How the data were processed

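Total RNA from the MDA-MB-231 breast cancer cell line was extracted with silica columns and sequenced on an Illumina instrument, per the labels' protocols. The library kit, any selection of polyadenylated RNA and the strand setting were not given in the sources used here. The 12 libraries fell into 4 groups of 3 by their treatment labels, and 0 per-sample columns remained without a sample. Dishes were plated in triplicate, and nothing said that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

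The authors deposited 1 table with raw read counts per gene, FPKM values, gene lengths and coordinates. The aligner HISAT2, without a version, and the build GRCh37/hg19 are named per the submitters' processing notes. The counting tool, its strand setting and the annotation release were not given in the sources used here. The deposited counts were whole numbers that summed to a different total in each library, between 15.3 and 25.4 M (mega). The deposited FPKM values served only as a check: the per-million totals recovered from them lay within 4.62% of the TMM-scaled totals of the counts. The authors' deposited table also gave log2 fold changes with p-values and adjusted p-values for 6 pairs of groups, made with a tool that was not given in the sources used here. The table held 57905 genes, of which 2023 had a gene name that occurred more than once, so genes were joined by Ensembl identifier. Without a stated strand setting, counts of overlapping or antisense genes such as RUSC1-AS1, C1RL-AS1 and LTB4R2 are uncertain, as are those of pseudogenes such as RWDD4P2, PFN1P1 and ZNF37BP that may share reads with their parent genes.

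Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr entered (15142 genes), libraries were scaled by TMM, and a mean per group was fitted to all 12 libraries with the robust quasi-likelihood F test, two-sided. The 6 comparisons were each treatment against vehicle, the combination against each single treatment, and the interaction, which is the combination effect minus the sum of the single effects on the log2 scale. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called. Standard errors of log2 fold changes were taken as the log2 fold change divided by the square root of F. CPM values were computed from TMM-scaled library totals, and their means and SD are over all 3 libraries of a group, also where a fit left out vehicle 2 and SFN 2. Values given after ± are SD over libraries for CPM and SE for log2 fold changes.

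Gene lists numbering 27 were fixed beforehand and 25 with at least 5 tested members were used. They held NRF2 target genes, mevalonate and cholesterol synthesis, prenyltransferases and small GTPases, YAP/TEAD target genes, the integrated stress response, ER chaperones, the heat shock response, mitosis, DNA replication, cell cycle inhibitors and p53 targets, apoptosis regulators, mesenchymal and epithelial markers, bone metastasis regulators, NF-kB and cytokine genes, interferon-stimulated genes, matrix proteases, hypoxia and glycolysis, autophagy and lysosome, DNA methylation and histone deacetylation enzymes, AP-1 and immediate early genes, mitochondrially encoded transcripts, ribosomal protein genes, histone genes and luminal breast cancer markers. The blood and immune cell list had 2 tested members and the fibroblast and endothelial list 4, so neither was tested. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 25 lists of a comparison, and again with the correlation estimated per list. fry was run beside it; its p asks whether the members move one way on balance and does not compare the list with other genes.

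Named genes followed a fixed rule. For each treatment against vehicle these were the 10 highest and 10 lowest log2 fold changes among called protein-coding genes with a mean of 1 CPM or more and no overlap of the groups, up to 3 called members of each list, and, with fewer than 10 such genes, those with the lowest unadjusted p until 10 were named. The other comparisons used 5 in place of 10. The genes NQO1, HMOX1, GCLM, TXNRD1, HMGCS1, FDPS and RHOB were reported in every comparison; some further genes that the rule named are not reported here. Further members given as examples of a list that no rule named, and SLC7A11 where it was not called, were chosen after their values were seen.

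Groups, comparisons, tests, lists, the rule for named genes and the following alternatives were chosen before the data were examined: DESeq2 size factors, the DESeq2 1.42.0 Wald test, no low-count filter, a filter of 1 CPM in 3 libraries, a fold minimum of 1.5, a fit of the compared groups alone, the replicate number as a block, the estimated list correlation and leaving out each library in turn. The following were chosen after seeing the data: fits without vehicle 2 and SFN 2 (10 libraries, 15353 genes), with a GC offset (12 libraries, 14747 genes), with both (14937 genes), with the GC offset on the compared groups alone, with a length offset added, with the replicate block on the SFN and vehicle libraries alone, and the direct comparison of ZA with SFN. The choice of vehicle 2 and SFN 2 came from the libraries' own values, and the fit that combined their removal with the GC offset gave the most calls of the settings run, so its results are given as secondary. The GC offset was a loess trend per library (span 0.3) of log2 deviations on GC content, fitted on genes above a log2 CPM of 1. GC content was that of each gene's longest transcript in GENCODE release 29, an annotation of another build matched by Ensembl identifier with no coordinates used, and 97.4% of tested genes had a value.

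The labels number the replicates without saying what a number marks. In SFN and vehicle, residuals from the group means of same-numbered libraries correlated at 0.792, 0.779 and 0.460 for numbers 1, 2 and 3. Those of vehicle 1 and SFN 3 (0.703) and of vehicle 3 and SFN 1 (0.548) correlated too. The data thus set only number 2 apart and do not show a pairing of 1 with 1 and 3 with 3. A block on these 6 libraries alone, without and with the GC offset, was added after seeing the data.

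Replicate libraries differed by more than sampling noise in every pair of a group, with a lowest chi-square per degree of freedom of 3.36 over genes with a count of at least 20, so no library was counted as a duplicate. The tests were tested on simulated counts with 200 changed genes drawn from the real means and library sizes. For SFN+ZA against vehicle with the spread of all 12 libraries (14901 genes), 1.49% of genes changed 1.5-fold, 14.9% of those changed 2-fold and 69.7% of those changed 4-fold were recovered, with 2 false calls. With the spread of the 10 libraries after the GC offset (14630 genes), these shares were 74.6%, 82.1% and 97.0%, with 10 false calls. For SFN+ZA against ZA the shares were 0%, 13.4% and 72.7% (14894 genes, 2 false calls) and 79.1%, 86.6% and 97.0% (14652 genes, 9 false calls). Each simulated library was drawn independently and without a GC trend, and the simulated counts were fitted without the GC offset. In the data residuals were correlated across groups. The shares and false calls therefore do not measure the power or error rate of the fits on the real libraries.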

Results

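RNA was sequenced from MDA-MB-231, a human triple-negative breast cancer cell line widely used to study metastasis. Cells were treated for 48 h with vehicle (DMSO and water), 1 µM SFN, 0.5 µM ZA or both compounds (SFN+ZA), with 3 libraries in each of 4 groups. SFN is a common abbreviation of sulforaphane, an isothiocyanate that activates the transcription factor NRF2, and ZA of zoledronic acid, a bisphosphonate that blocks farnesyl diphosphate synthase. The labels spell out neither name, and the treatment SFN is distinct from the gene of that symbol. Total counts per library (M, mega) were 15.3, 17.2 and 16.7 M in vehicle 1, 2 and 3, and 15.7, 18.3 and 16.3 M in SFN 1, 2 and 3. They were 19.2, 25.4 and 15.9 M in ZA 1, 2 and 3, and 16.5, 17.6 and 16.1 M in SFN+ZA 1, 2 and 3. Protein-coding genes took 95.8 to 97.9% of the counts. Gene positions are those of the authors' deposited table on GRCh37/hg19.

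SFN 2 and vehicle 2 stood apart from the other 10 libraries. The first principal component held 70.4% of the variance and placed SFN 2 at 169.9 and vehicle 2 at 67.4, with the others between -47.5 and -3.99. Across genes, which are not independent replicates, Spearman's rho between GC content and the deviation from the median library was -0.838 in SFN 2 and -0.664 in vehicle 2. It ranged from -0.579 in ZA 1 to 0.731 in SFN+ZA 1 in the others. In SFN 1 and 3 it was -0.527 and -0.531, and in SFN+ZA 2 and 3 it was 0.276 and 0.444. SFN and SFN+ZA thus did not overlap in GC trend, even without SFN 2. Mitochondrially encoded genes took 0.775% of counts in vehicle 2 and 1.60% in SFN 2, against 1.89 to 5.30% elsewhere. The 28S ribosomal RNA gene RNA28S5 took 0.0161% of counts in SFN 2 and 0.337 to 2.06% in the other 11. Both libraries entered all tests unless stated otherwise.

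**Figure D1:**
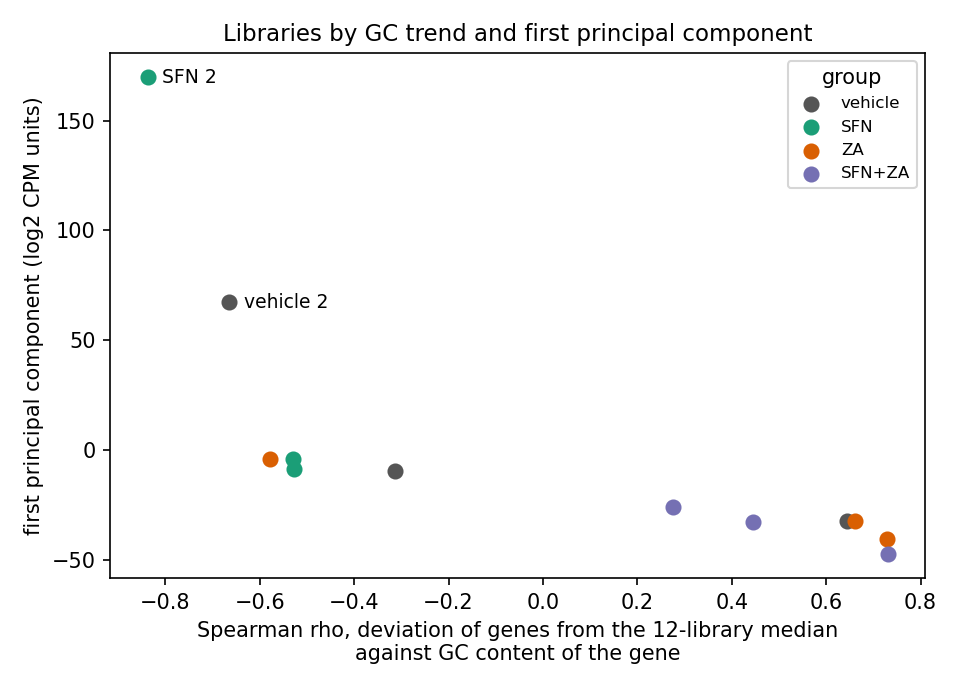
Spearman's rho between GC content and each library's deviation from the median library (horizontal axis) and first principal component of log2 CPM (vertical axis), 1 point per library, coloured by group. SFN 2 (-0.838, 169.9) and vehicle 2 (-0.664, 67.4) lie above and to the left of the other 10 libraries.

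The comparison of SFN with vehicle asks what SFN alone does to transcript levels. Mitochondrially encoded transcripts, which code for respiratory chain subunits, rose as a group: their median log2 fold change was 0.76 and 13 of 13 members lay above 0 (camera adjusted p = 0.012; adjusted p = 0.68 with an estimated correlation). Ribosomal protein genes fell as a group, with a median of -0.32 and 20 of 24 members below 0 (adjusted p = 0.012; adjusted p = 0.57 with an estimated correlation). Among them RPL3 had a log2 fold change of -0.35 ± 0.15 and RPS9 of -0.53 ± 0.25. Hypoxia and glycolysis genes fell as a group, with a median of -0.19 and 23 of 29 members below 0 (adjusted p = 0.016; adjusted p = 0.63 with an estimated correlation). The glycolytic enzyme ENO1 measured 3811 ± 345 CPM in vehicle and 2822 ± 691 in SFN (SD, n = 3 each). No single member of these lists passed, over all genes or adjusted over the list alone, and fry called 0 of the 25 lists.

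NRF2 target genes did not pass after SFN alone with all 12 libraries and no offset, with a median of 0.04 and 16 of 31 members above 0 (adjusted p = 0.46). Their member SLC7A11, the cystine transporter subunit (ENSG00000151012, chromosome 4, 139085251 to 139163503), measured 115 ± 12.4 CPM in vehicle and 171 ± 17.8 in SFN (SD, n = 3 each). Its log2 fold change of 0.57 ± 0.16 did not pass (adjusted p = 0.73), and it overlaps SLC7A11-AS1, so its count is uncertain without strand. The genes with the lowest unadjusted p were led by DDX26B (ENSG00000165359, chromosome X, 134654584 to 134716435), at 3.56 ± 0.284 CPM in vehicle and 6.72 ± 0.245 in SFN (SD, n = 3 each), a log2 fold change of 0.91 ± 0.18. The secretory granule protein gene SCG5 (0.87 ± 0.20), RWDD4P2 (1.10 ± 0.25) and RP11-658F2.8 (1.02 ± 0.27) also had positive values. The MHC class II gene HLA-DRA measured 24.5 ± 1.38 CPM in vehicle and 16.6 ± 1.76 in SFN, a log2 fold change of -0.56 ± 0.14. Negative values were also estimated for RGN (-1.56 ± 0.35), KIAA1199 (-0.55 ± 0.15), CHCHD1 (-0.58 ± 0.15), AP1S1 (-0.68 ± 0.18) and CCDC3 (-0.55 ± 0.15).

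edgeR called 0 of 15142 genes in SFN against vehicle (lowest adjusted p = 0.73), with 753 at an unadjusted p under 0.05 where 757 would be expected by chance, and DESeq2 called 0. With the GC offset the median of ribosomal protein genes moved to -0.09 (adjusted p = 0.29) and that of hypoxia and glycolysis genes to -0.04 (adjusted p = 0.57); without vehicle 2 and SFN 2 the former stayed lower with 18 of 24 members below 0 (median -0.20, adjusted p = 0.0043; adjusted p = 0.34 with an estimated correlation) and the latter was -0.11 (adjusted p = 0.067). With the replicate number as a block on the SFN and vehicle libraries alone, 5 lists passed in place of 3: the same 3 and, lower in SFN, epithelial markers (median -0.50, adjusted p = 0.017) and AP-1 and immediate early genes (-0.31, adjusted p = 0.044), each with adjusted p = 0.72 with an estimated correlation. Adding the GC offset to that block moved ribosomal protein genes to -0.08 (adjusted p = 0.45), hypoxia and glycolysis genes to -0.03 (adjusted p = 0.54), epithelial markers to 0.03 (adjusted p = 0.88) and AP-1 and immediate early genes to adjusted p = 0.60.

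The GC offset on all 12 libraries also called lists for SFN that had not passed without it. NRF2 target genes rose (median 0.10, 25 of 31 members above 0, adjusted p = 0.035), as did heat shock genes (0.19, 13 of 14 above 0, adjusted p = 0.0071), and mevalonate and cholesterol synthesis genes fell (-0.11, 22 of 26 below 0, adjusted p = 0.026). With an estimated correlation their adjusted p values were 0.29, 0.52 and 0.29. The block with the GC offset called the same lists, with medians of 0.08 (adjusted p = 0.019), 0.16 (adjusted p = 0.0056) and -0.12 (adjusted p = 0.019), and with an estimated correlation their adjusted p values there were 0.83, 0.84 and 0.83. On 10 libraries with the GC offset heat shock genes (0.03, adjusted p = 0.80) and mevalonate genes (-0.04, adjusted p = 0.16) did not pass. With the GC offset and 10 libraries, the splicing helicase gene DDX39B (0.59 ± 0.09) and the glycosyltransferase gene OGT (0.47 ± 0.07) were called (adjusted p = 0.041 for each). The value of DDX39B was 0.09 with all 12 libraries and turned negative without SFN 1 (-0.05) or SFN 3 (-0.16). In OGT the left-out SFN 2 measured 185 CPM, within the 183 to 248 CPM of the vehicle libraries. In the fit of both steps NRF2 target genes rose with a median of 0.09 and 7 members adjusted over the list alone (adjusted p = 4.1e-04; adjusted p = 0.22 with an estimated correlation). On the 10 libraries without the offset the NRF2 list did not pass (0.11, adjusted p = 0.080). With the replicate block and no offset its median was -0.02 on all 12 libraries (adjusted p = 0.42) and -0.03 on the SFN and vehicle libraries alone (adjusted p = 0.56), so no direction of it is read for SFN. In the fit of both steps epithelial markers fell with a median of -0.12 (adjusted p = 0.0084; adjusted p = 0.22 with an estimated correlation), but with the GC offset on all 12 libraries their median was 0.06 with 11 of 18 members above 0 (adjusted p = 0.90), so no direction is read from them.

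The comparison of ZA with vehicle asks the same of ZA alone, against the same 3 vehicle libraries. Mitochondrially encoded transcripts rose as a group by a median log2 fold change of 1.39, with 13 of 13 members above 0 (adjusted p = 3.1e-20; adjusted p = 0.47 with an estimated correlation). The cytochrome c oxidase subunit gene MT-CO1 (ENSG00000198804, chromosome MT, 5904 to 7445) measured 4126 ± 2312 CPM in vehicle and 9191 ± 499.8 in ZA (SD, n = 3 each), a log2 fold change of 1.16 ± 0.34 that did not pass on its own (adjusted p = 0.98). DNA replication genes fell as a group, with a median of -0.14 and 19 of 24 members below 0 (adjusted p = 0.0099; adjusted p = 0.58 with an estimated correlation). Examples were CCNE1 (-0.35 ± 0.19) and the helicase subunit gene MCM6 (-0.30 ± 0.20). No single member of either list passed, over all genes or adjusted over the list alone. Mevalonate and cholesterol synthesis genes, the pathway of farnesyl diphosphate synthase, had a median of -0.06 (adjusted p = 0.44) and NRF2 target genes of -0.06 (adjusted p = 0.32), and neither list passed.

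The gene with the lowest unadjusted p after ZA was SLC25A27, which encodes a mitochondrial carrier (ENSG00000153291, chromosome 6, 46620678 to 46645930), at 7.53 ± 1.34 CPM in vehicle and 13.3 ± 0.748 in ZA (SD, n = 3 each). Its log2 fold change was 0.82 ± 0.17 (adjusted p = 0.98). The lincRNA RP11-159D12.2 (ENSG00000264112, chromosome 17, 56066400 to 56072211) had a log2 fold change of 0.89 ± 0.20. LTB4R2 (1.62 ± 0.38), which overlaps LTB4R, POU5F1 (1.29 ± 0.32), RP11-658F2.8 (1.05 ± 0.27), PRSS16 (0.93 ± 0.27) and C1RL-AS1 (1.25 ± 0.37) also had positive values, as did the mitochondrial MT-RNR2 (0.80 ± 0.22) and MT-ND4L (1.54 ± 0.49).

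edgeR called 0 of 15142 genes in ZA against vehicle (lowest adjusted p = 0.98), with 173 at an unadjusted p under 0.05, and DESeq2 called 0. By chance 757 would be expected, so the p-values ran high here and the 0 calls do not show that no gene changed. Without vehicle 2 and SFN 2 the DNA replication list no longer passed (median -0.05, adjusted p = 0.11), while the mitochondrial list kept a median of 0.91 (adjusted p = 1.1e-54; adjusted p = 0.036 with an estimated correlation). On 10 libraries with the GC offset 19 genes rose and 0 fell, among them RP11-159D12.2 (1.12 ± 0.14, adjusted p = 0.010), SLC25A27 (1.00 ± 0.16, adjusted p = 0.018), OGT (0.48 ± 0.06, adjusted p = 0.010), DDX39B (0.56 ± 0.08, adjusted p = 0.013) and the efflux transporter gene ABCC3 (0.46 ± 0.08, adjusted p = 0.022). The same fit called GABRE, PABPC1L, SPEG, GABBR1, CCNL2 and SLC26A6, with log2 fold changes of 0.72, 0.67, 0.67, 0.61, 0.56 and 0.46. The left-out vehicle 2 lay within the ZA range in OGT (248 CPM against 236 to 277) and in CCNL2 (94.5 against 90.8 to 98.4). Ribosomal protein genes also fell in it, with a median of -0.06 (adjusted p = 0.028; adjusted p = 0.39 with an estimated correlation).

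The comparison of SFN+ZA with vehicle asks what the combination does. Mitochondrially encoded transcripts rose as a group by a median log2 fold change of 1.51, with 13 of 13 members above 0 and 1 called adjusted over the list alone (adjusted p = 6.5e-13; adjusted p = 0.25 with an estimated correlation). MT-CO1 measured 4126 ± 2312 CPM in vehicle and 11063 ± 841 in SFN+ZA (SD, n = 3 each). The mitochondrial share of counts was 4.69, 5.00 and 5.30% in SFN+ZA 1, 2 and 3, against 3.27, 0.775 and 1.89% in vehicle 1, 2 and 3. RNA28S5 took 0.519, 0.491 and 0.337% in the same SFN+ZA libraries, against 2.06, 0.585 and 1.46% in vehicle. The list without vehicle 2 and SFN 2 had a median of 1.08. The rises of this list in SFN, ZA and SFN+ZA rest on the same 3 vehicle libraries and are not separate results.

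**Figure D2:**
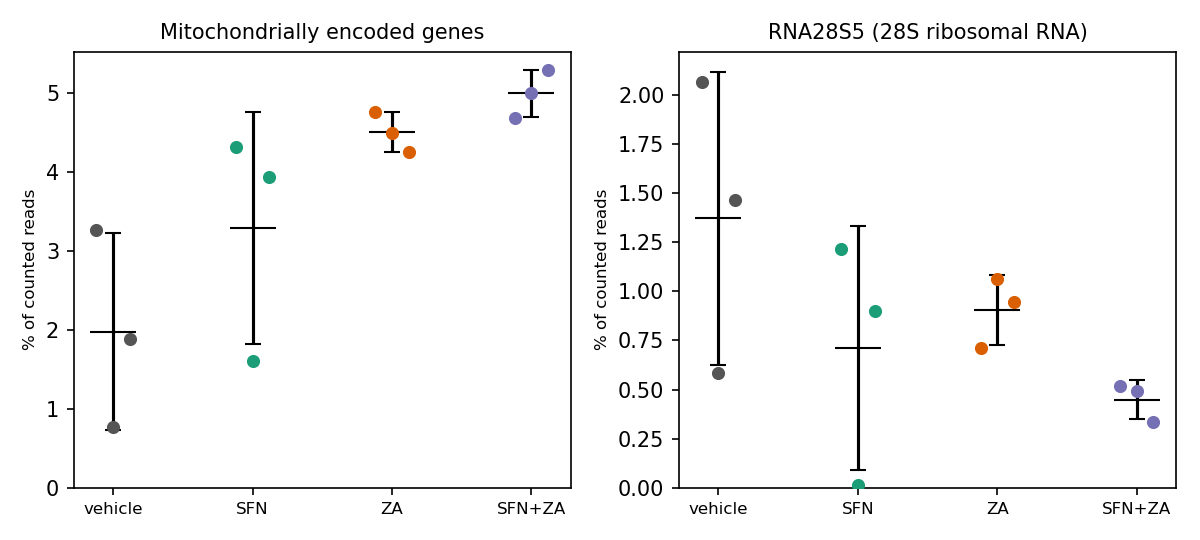
Percent of each library's counted reads in mitochondrially encoded genes (first panel) and in the 28S ribosomal RNA gene RNA28S5 (second panel), by group, with 1 point per library, a line at the mean and bars of 1 SD (n = 3). Vehicle 2 (0.775%) and SFN 2 (1.60%) had the lowest mitochondrial shares of their groups, and the SFN+ZA libraries lay between 4.69 and 5.30%.

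The genes with the lowest unadjusted p in the combination were RP11-159D12.2, at 17.8 ± 4.44 CPM in vehicle and 45.7 ± 7.11 in SFN+ZA (SD, n = 3 each), and SLC25A27, at 7.53 ± 1.34 and 16.5 ± 1.59. Their log2 fold changes were 1.36 ± 0.20 and 1.13 ± 0.18 (adjusted p = 0.34 for both). NPIPB5 (ENSG00000243716, chromosome 16, 22490442 to 22547842) had 0.93 ± 0.17 but belongs to a family of near-identical copies and overlaps SMG1P1, so its count is uncertain. The axon guidance gene SEMA5A (ENSG00000112902, chromosome 5, 9035138 to 9546187) measured 12.2 ± 2.10 CPM in vehicle and 6.11 ± 1.13 in SFN+ZA, a log2 fold change of -1.0 ± 0.20. LTB4R2 (2.35 ± 0.38), C1orf132 (1.59 ± 0.33), RP11-449P15.2 (1.36 ± 0.29), RUSC1-AS1 (1.25 ± 0.26), RP4-555D20.2 (1.11 ± 0.23) and ZNF37BP (0.71 ± 0.15) had positive values.

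The other lists did not pass in SFN+ZA against vehicle. Interferon-stimulated genes had a median of -0.21, matrix proteases of -0.19, bone metastasis regulators of -0.25 and ribosomal protein genes of -0.13 (camera adjusted p = 0.069 for each); fry called the interferon list alone (adjusted p = 0.023). DNA replication genes had a median of -0.10 (adjusted p = 0.070), prenyltransferases and small GTPases of -0.13 (adjusted p = 0.11), mevalonate and cholesterol synthesis genes of -0.14 (adjusted p = 0.12) and NRF2 target genes of 0.09 (adjusted p = 0.44). Medians were 0.24 for the integrated stress response, 0.21 for AP-1 and immediate early genes, 0.17 for NF-kB and cytokine genes, 0.12 for DNA methylation and histone deacetylation enzymes and 0.08 for hypoxia and glycolysis. They were -0.12 for mitosis, -0.08 for ER chaperones, -0.08 for the heat shock response, -0.07 for autophagy and lysosome and -0.07 for histone genes. The remaining medians were 0.01 for YAP/TEAD targets, -0.03 for p53 targets, -0.03 for apoptosis regulators, 0.00063 for mesenchymal markers, 0.02 for epithelial markers and 0.11 for luminal breast cancer markers, a check on another cell type (adjusted p = 0.96 for the last).

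edgeR called 0 of 15142 genes in SFN+ZA against vehicle (lowest adjusted p = 0.34), with 744 at an unadjusted p under 0.05. The DESeq2 Wald test called 15 genes higher and 1 lower. Leaving out SFN 2 alone gave 19 calls in edgeR, leaving out vehicle 2 and SFN 2 gave 51 higher and 1 lower, the GC offset on 12 libraries gave 2, the GC offset on the compared groups alone gave 17, and both steps together gave 368 higher and 88 lower.

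In that last fit, chosen after seeing the data, several transcripts differed between SFN+ZA and vehicle. ABCC3 (ENSG00000108846, chromosome 17, 48712138 to 48769613), an NRF2 target that encodes an organic anion exporter, measured 76.8 ± 10.2 CPM in vehicle and 151 ± 20.3 in SFN+ZA (SD, n = 3 each) and rose by 0.86 ± 0.08 (adjusted p = 2.3e-05). SLC7A11 rose by 0.38 ± 0.06 (adjusted p = 0.0023). NRF2 target genes rose as a group, with a median of 0.08, 25 of 31 members above 0, 2 called over all genes and 3 adjusted over the list alone (adjusted p = 0.011; adjusted p = 0.14 with an estimated correlation). Interferon-stimulated genes fell, with a median of -0.14, 21 of 25 members below 0 and 3 called (adjusted p = 2.0e-04; adjusted p = 0.083 with an estimated correlation). IFIT3 went from 126 ± 3.68 to 96.5 ± 7.81 CPM and IFIT1 from 81.5 ± 12.6 to 55.8 ± 4.34 (SD, n = 3 each); each had a log2 fold change of -0.36 (adjusted p = 0.0062 and 0.023). Means of CPM include vehicle 2, which this fit leaves out; with all 12 libraries and no offset the log2 fold changes were -0.39 for IFIT3 and -0.55 for IFIT1. Both overlap LIPA. ISG15 fell by 0.34 ± 0.08 in the fit (adjusted p = 0.039), but averaged 83.8 ± 14.1 CPM in vehicle and 76.7 ± 9.49 in SFN+ZA. Its groups overlapped with and without vehicle 2, since vehicle 3 (84.1 CPM) lay below SFN+ZA 1 (86.4 CPM).

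The mevalonate and cholesterol synthesis list fell slightly, with a median of -0.08 (adjusted p = 0.014; adjusted p = 0.14 with an estimated correlation). Prenyltransferases and small GTPases, whose products carry or attach isoprenoid anchors, fell with a median of -0.12 and 17 of 20 members below 0 (adjusted p = 0.0053; adjusted p = 0.083 with an estimated correlation), and CDC42 fell by 0.27 ± 0.06 (adjusted p = 0.021). Matrix proteases and inhibitors fell with a median of -0.10 (adjusted p = 0.011; adjusted p = 0.088 with an estimated correlation), with TIMP3 at -0.25 ± 0.06 and CTSB at -0.25 ± 0.06. Ribosomal protein genes (median -0.12, adjusted p = 2.0e-04), epithelial markers (-0.12, adjusted p = 0.019) and bone metastasis regulators (-0.08, adjusted p = 0.025) also fell. With an estimated correlation their adjusted p values were 0.083, 0.10 and 0.11. With all 12 libraries and no offset, epithelial markers had a median of 0.02 with 12 of 18 members above 0 (camera adjusted p = 0.96). No direction is therefore read from epithelial markers. The mitochondrial list rose with a median of 1.12, 2 members called over all genes and 12 adjusted over the list alone (adjusted p = 2.1e-26; adjusted p = 0.083 with an estimated correlation).

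Among single genes of the same fit, the BMP target and transcriptional inhibitor ID3 (ENSG00000117318, chromosome 1, 23884409 to 23886285) went from 11.5 ± 1.69 to 6.50 ± 1.17 CPM (SD, n = 3 each) and fell by 0.97 ± 0.19 (adjusted p = 0.011). Over the 10 libraries its log2 CPM in SFN+ZA did not overlap that in vehicle, and PRELP (-1.18 ± 0.27), SEMA5A (-0.82 ± 0.17), C1QL1 (-0.86 ± 0.20), RPS29 (-0.74 ± 0.16, overlapping RN7SL1), ATOH8 (-0.71 ± 0.14) and CLIC3 (-0.62 ± 0.10) fell too. CLDN2, PLSCR4 and C10orf54 completed the lowest 10, at -0.56, -0.55 and -0.54. The highest log2 fold changes were those of EGFL8 (2.36 ± 0.55), ILK (2.17 ± 0.42, overlapping TAF10), TBC1D29 (1.84), MC1R (1.82), TIAF1 (1.65), SNX15 (1.63), BTBD19 (1.54), GSDMB (1.51), MT-ATP8 (1.5 ± 0.32, overlapping MT-ATP6) and YJEFN3 (1.45). All had low counts in vehicle, so the size of these changes is uncertain. Vehicle means in the same order were 0.412, 0.501, 0.391, 0.746, 1.11, 0.661, 1.09, 1.05, 0.896 and 2.60 CPM. Called members of other lists were VEGFA (0.38 ± 0.08), the RAS pathway inhibitor SPRY4 (0.39 ± 0.07), LIF (0.44 ± 0.11), PLK3 (0.45), TET3 (0.47), HDAC6 (0.34), DOCK5 (0.28), TGFB2 (-0.23), BMP4 (-0.24), KRT8 (-0.29) and MT-ND2 (0.95 ± 0.18). The direction of KRT8 was opposite with all 12 libraries and no offset. With all 12, C1QL1, CLIC3 and C10orf54 stood at -0.15, -0.17 and -0.20, and without vehicle 1 they turned to 0.24, 0.16 and 0.07. Vehicle 2 lay below every SFN+ZA library in these 3 genes, in ATOH8 and in KRT8, and within their range in CLDN2, TIAF1 and SLC7A11, so the groups were apart in all of these only without it. The 368 genes called higher included 43 of the 51 called without vehicle 2 and SFN 2, 13 of the 15 called by DESeq2 and 17 of the 19 called without SFN 2 alone.

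**Figure D3:**
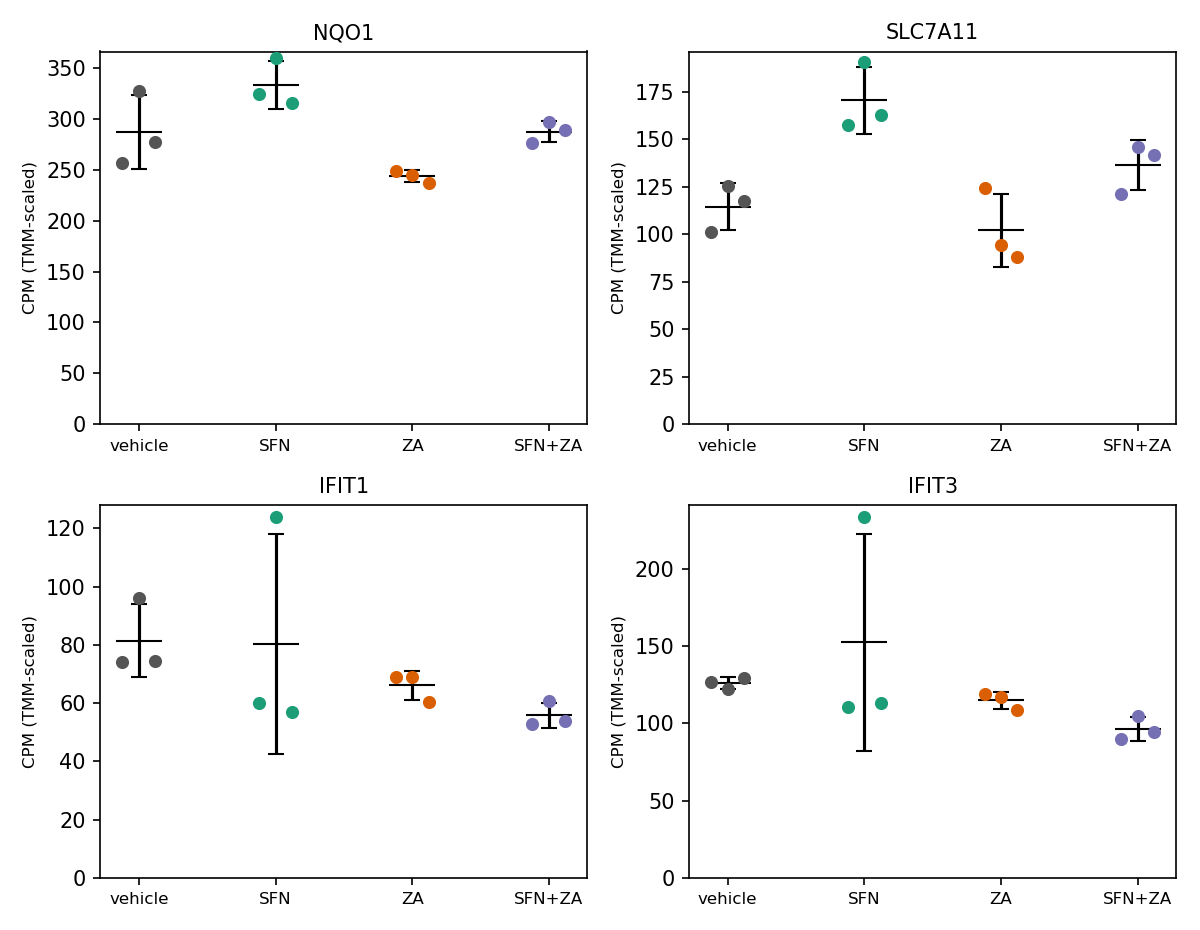
TMM-scaled CPM of NQO1, SLC7A11, IFIT1 and IFIT3 in each library by group, with 1 point per library, a line at the mean and bars of 1 SD (n = 3). IFIT3 averaged 126 CPM in vehicle and 96.5 in SFN+ZA, and SFN 2 stood at 234 CPM, above every other library.

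The comparison of SFN+ZA with SFN asks what adding ZA to SFN changes. The lncRNA NEAT1, a scaffold of nuclear paraspeckles (ENSG00000245532, chromosome 11, 65190245 to 65213011), measured 177 ± 52.7 CPM in SFN and 428 ± 96.8 in SFN+ZA (SD, n = 3 each), a log2 fold change of 1.28 ± 0.27 that did not pass (adjusted p = 0.22). The zinc finger gene ZNF337 (1.62 ± 0.33) and NPIPB5 (0.79 ± 0.17) had positive values among the lowest unadjusted p. RP11-359B12.2 (-1.56 ± 0.33) and RP11-254B13.1 (-1.06 ± 0.22) had negative ones. No list passed camera; the lowest adjusted p of 0.063 was shared by mitosis genes (median -0.37), AP-1 and immediate early genes (0.39) and mitochondrially encoded transcripts (0.70), and fry called ER chaperones (adjusted p = 0.044).

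edgeR called 0 of 15142 genes in SFN+ZA against SFN (lowest adjusted p = 0.22), with 974 higher and 2338 lower at an unadjusted p under 0.05, and DESeq2 called 0. The excess of lower genes was absent without vehicle 2 and SFN 2 (1838 higher and 1761 lower) and with the GC offset added to that (1475 and 1481). The GC trend parted every SFN library from every SFN+ZA library, so what the offset removes cannot be told apart from treatment here. On 10 libraries with the GC offset 23 genes rose and 9 fell, among them PABPC1L (ENSG00000101104, chromosome 20, 43538703 to 43587676, overlapping TOMM34; 0.85 ± 0.10, adjusted p = 0.0063), NPIPB5 (0.61 ± 0.10, adjusted p = 0.024), ZNF814 (1.27 ± 0.22, adjusted p = 0.031) and the leukotriene receptor gene LTB4R (0.98 ± 0.16, adjusted p = 0.033). CCDC84 (0.86 ± 0.15) and SHOX2 (0.68 ± 0.13) rose, and PSMA1 (-0.70 ± 0.13), NENF (-0.58 ± 0.10), MRPL14 (-0.51 ± 0.09), ZNF639 (-0.45 ± 0.08) and TMEM219 (-0.43 ± 0.08) fell; the sign of TMEM219 was opposite with all 12 libraries. NENF and MRPL14 stood at -0.10 and -0.12 with all 12 and at 0.07 and 0.0073 without SFN 3, and SFN 2 lay below every SFN+ZA library in both. The mitochondrial list rose with a median of 0.33 in that fit (adjusted p = 0.0051; adjusted p = 0.70 with an estimated correlation).

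The comparison of SFN+ZA with ZA asks what adding SFN to ZA changes. It involves neither vehicle 2 nor SFN 2 except through the shared estimate of the spread, the scaling and the gene filter. NRF2 target genes rose as a group, with a median log2 fold change of 0.16 and 24 of 31 members above 0 (adjusted p = 0.0029; adjusted p = 0.058 with an estimated correlation). SLC7A11 measured 102 ± 19.3 CPM in ZA and 136 ± 13.2 in SFN+ZA, and the quinone reductase gene NQO1 (ENSG00000181019, chromosome 16, 69740899 to 69760854) 244 ± 6.23 and 288 ± 10.8 (SD, n = 3 each). Their log2 fold changes were 0.42 ± 0.16 and 0.24 ± 0.12, and those of AKR1C1 and GCLC 0.73 ± 0.37 and 0.32 ± 0.22. In SLC7A11 the groups overlapped, with ZA 1 at 124 CPM and SFN+ZA 1 at 121 CPM. Interferon-stimulated genes fell as a group, with a median of -0.17 and 19 of 25 members below 0 (adjusted p = 0.020; adjusted p = 0.098 with an estimated correlation), as in IFIH1 (-0.27 ± 0.16) and OASL (-0.25 ± 0.21). No single member of either list passed, over all genes or adjusted over the list alone, and fry called 0 lists.

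Single genes with the lowest unadjusted p were SEMA5A, at 10.3 ± 0.986 CPM in ZA and 6.11 ± 1.13 in SFN+ZA (log2 fold change -0.75 ± 0.20), NPIPB5 (0.62 ± 0.17), RBM15, a cofactor of RNA methylation (0.46 ± 0.13), the ubiquitin ligase gene HECW1 (0.66 ± 0.19) and RP11-254B13.1 (-0.84 ± 0.22). edgeR called 0 of 15142 genes, with 159 at an unadjusted p under 0.05 where 757 would be expected by chance, and DESeq2 called 0.

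Both lists passed with the GC offset on 12 libraries, on the 10 libraries and with both steps. With an estimated correlation each had adjusted p = 0.031 with the GC offset on 12 libraries and adjusted p = 0.081 on the 10 libraries. With both steps the NRF2 median was 0.13, with 24 of 31 members above 0, 2 called over all genes and 6 adjusted over the list alone (adjusted p = 6.5e-08; adjusted p = 0.048 with an estimated correlation), and the interferon median was -0.17 with 21 of 25 members below 0 and 2 called adjusted over the list alone (adjusted p = 1.8e-05; adjusted p = 0.043 with an estimated correlation). SLC7A11 (0.49 ± 0.05, adjusted p = 8.7e-04), OGT (0.47 ± 0.06, adjusted p = 0.0026), PABPC1L (0.68 ± 0.09, adjusted p = 0.0051), NPIPB5 (0.62 ± 0.09, adjusted p = 0.0089), NKTR (0.42 ± 0.07, adjusted p = 0.026), ABCC3 (0.40 ± 0.07, adjusted p = 0.032) and the GABA receptor gene GABBR1 (0.52 ± 0.09, adjusted p = 0.038) rose. The matrix protein gene MATN2, which overlaps RPL30, fell by 0.41 ± 0.07 (adjusted p = 0.038), so 7 genes rose and 2 fell in all. The integrated stress response list rose with a median of 0.20 and 15 of 18 members above 0 (adjusted p = 6.3e-04; adjusted p = 0.20 with an estimated correlation). Mevalonate synthesis genes (-0.06, adjusted p = 0.012), ribosomal protein genes (-0.06, adjusted p = 0.017) and epithelial markers (-0.09, adjusted p = 0.042) fell, each with adjusted p = 0.19 with an estimated correlation.

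The interaction asks whether the combination differs from the sum of the single effects. The myosin gene MYH3 had the lowest unadjusted p, with means of 5.81 CPM in vehicle, 4.10 in SFN, 4.95 in ZA and 7.27 in SFN+ZA and an interaction of 1.05 ± 0.28 on the log2 scale (adjusted p = 0.90). COCH (-1.52 ± 0.43), which overlaps STRN3, RWDD4P2 (-1.23 ± 0.35), RGN (1.69 ± 0.48) and PFN1P1 (-1.43 ± 0.41) followed. Mitochondrially encoded transcripts had a median of -0.54 with 13 of 13 members below 0 and did not pass (adjusted p = 0.16). Low values of these transcripts in the shared vehicle libraries could alone give this sign. edgeR called 0 of 15142 genes, with 257 at an unadjusted p under 0.05 where 757 would be expected by chance. DESeq2 called 0, and camera and fry called 0 lists. Without vehicle 2 and SFN 2 the mitochondrial list passed at a median of -0.56 (adjusted p = 4.6e-10; adjusted p = 0.91 with an estimated correlation).

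Of 9 genes named beforehand 7 are reported, and none of these 7 passed in any of the 6 comparisons with all 12 libraries. NQO1 measured 287 ± 36.3 CPM in vehicle, 333 ± 23.6 in SFN, 244 ± 6.23 in ZA and 288 ± 10.8 in SFN+ZA (SD, n = 3 each). Its log2 fold changes against vehicle were 0.22 ± 0.12, -0.24 ± 0.12 and 0.00 ± 0.12. Heme oxygenase gene HMOX1 (ENSG00000100292, chromosome 22, 35776354 to 35790207) measured 13.0 ± 5.53, 8.37 ± 5.73, 15.0 ± 4.93 and 17.2 ± 2.47 CPM in the same order of groups. GCLM, a subunit of the enzyme that starts glutathione synthesis, measured 184 ± 35.9, 242 ± 68.6, 161 ± 21.6 and 172 ± 16.3 CPM, and TXNRD1 1194 ± 181, 1346 ± 281, 1082 ± 10.6 and 1134 ± 36.7. The sterol-regulated gene HMGCS1 measured 105 ± 24.6, 121 ± 29.6, 96.9 ± 12.2 and 93.5 ± 1.61 CPM. FDPS, which encodes farnesyl diphosphate synthase and overlaps RUSC1-AS1, measured 102 ± 11.9, 73.2 ± 10.4, 91.4 ± 10.6 and 92.6 ± 9.03 CPM, and RHOB 54.9 ± 8.82, 45.7 ± 10.8, 53.5 ± 6.21 and 53.1 ± 1.72.

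Log2 fold changes of SFN against vehicle were -0.64 ± 0.55 for HMOX1, 0.39 ± 0.21 for GCLM, 0.17 ± 0.16 for TXNRD1, 0.20 ± 0.20 for HMGCS1, -0.48 ± 0.16 for FDPS and -0.26 ± 0.19 for RHOB. Those of ZA were 0.20 ± 0.55, -0.19 ± 0.21, -0.14 ± 0.16, -0.11 ± 0.20, -0.16 ± 0.16 and -0.04 ± 0.19 for the same genes. For SFN+ZA against vehicle the values were 0.40 ± 0.55 for HMOX1, -0.10 ± 0.21 for GCLM, -0.07 ± 0.16 for TXNRD1, -0.16 ± 0.20 for HMGCS1, -0.14 ± 0.16 for FDPS and -0.05 ± 0.19 for RHOB. Against SFN they were -0.21 ± 0.12 for NQO1 and, in the same order of genes, 1.04 ± 0.55, -0.49 ± 0.21, -0.25 ± 0.16, -0.37 ± 0.20, 0.34 ± 0.16 and 0.21 ± 0.19. Against ZA the values of the same 6 genes lay between -0.05 ± 0.20 (HMGCS1) and 0.20 ± 0.54 (HMOX1). The interaction was 0.02 ± 0.17 for NQO1, 0.84 ± 0.78 for HMOX1, -0.30 ± 0.30 for GCLM, -0.10 ± 0.23 for TXNRD1, -0.26 ± 0.29 for HMGCS1, 0.50 ± 0.23 for FDPS and 0.25 ± 0.28 for RHOB. The signs of GCLM, TXNRD1, HMGCS1, FDPS and RHOB turned in at least 1 comparison with the GC offset and that of HMOX1 without vehicle 2 and SFN 2, so no direction is read from them.

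Calls of SFN and of ZA against the same vehicle libraries were 0 in common with all 12 libraries. Across genes, which are not independent, the log2 fold changes of both comparisons had r = 0.0798 and a covariance of 0.0131. Unchanged groups simulated against shared controls gave r = 0.501 and a covariance of 0.0962 on average over 20 simulations. The simulations drew each library independently, but in the data residuals were correlated across groups. Those of vehicle 2 and SFN 2 had r = 0.779, and those of vehicle 1 and ZA 1 had r = -0.730. Neither the observed r nor the covariance can therefore be judged against the simulations. Those with 10 libraries drew each library in the same way. With the GC offset and 10 libraries DDX39B, whose sign for SFN turned when SFN 1 or SFN 3 was left out of all 12, and OGT were called in both comparisons, 2 genes where independent lists would share 0.00254, with r = 0.572 and a covariance of 0.0800 against 0.558 and 0.0438 in the simulations. In OGT the left-out SFN 2 lay within the vehicle range and the left-out vehicle 2 within the ZA range. The 3 vehicle libraries were too few to be split, so part of any excess may come from the shared controls.

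A direct comparison of ZA with SFN, added after seeing the data, called 0 of 15142 genes in edgeR (1804 at an unadjusted p under 0.05), as the authors' deposited table did, and camera called 0 lists. fry called ER chaperones (adjusted p = 0.031; median -0.18). On 10 libraries with the GC offset NRF2 target genes were lower in ZA than in SFN, with a median of -0.14 and 27 of 31 members below 0, 1 called over all genes and 7 adjusted over the list alone (adjusted p = 3.7e-09; adjusted p = 0.063 with an estimated correlation). In the same fit the integrated stress response (-0.07, adjusted p = 0.0034) and ER chaperones (-0.07, adjusted p = 0.038) had negative medians, and epithelial markers (0.08, adjusted p = 0.044) and mitochondrially encoded transcripts (0.17, adjusted p = 0.038) positive ones. With an estimated correlation these adjusted p values were 0.46, 0.25, 0.25 and 0.84. The integrated stress response had the opposite sign with all 12 libraries (median 0.33, 14 of 18 members above 0, adjusted p = 0.60), and epithelial markers with the GC offset on all 12 (-0.03, adjusted p = 0.78), so no direction is read from either.

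The authors' deposited table held 42 higher and 2 lower genes for SFN+ZA against vehicle at an adjusted p under 0.05. Those with the lowest adjusted p in the authors' deposited table included PABPC1L (log2 fold change 1.39, adjusted p = 1.9e-10) and GABBR1 (1.28, adjusted p = 1.5e-05). RP11-159D12.2 (1.35), NEAT1 (1.26) and ABCC3 (0.97) were also among them, MT-CO1 (1.42) passed with adjusted p = 0.042, and RNA28S5 (-1.63) and RPS29 (-1.05) were the lower pair in the authors' deposited table. edgeR called 38 of the 44 with the GC offset and 10 libraries, and 0 with all 12 libraries. Against SFN, the authors' deposited table held 9 genes higher and 1 lower in SFN+ZA, led by FAM207A (2.73, adjusted p = 8.8e-09), and edgeR called 0 of these 10 in either fit. For SFN+ZA against ZA the authors' deposited table held 4 higher and 7 lower, with RNA28S5 (-1.04, adjusted p = 5.7e-05) and RPS29 (-0.79, adjusted p = 9.9e-05) lower and PABPC1L (0.69) higher; edgeR called 3 of these 11 with the GC offset and 10 libraries and 0 with all 12. SFN and ZA alone had 0 genes in the authors' deposited table, with 165 and 318 at an unadjusted p under 0.05. Log2 fold changes of edgeR and of the authors' deposited table correlated across genes with r of 0.99977 or higher in every comparison they share.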

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

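Tests without vehicle 2 and SFN 2, those with a GC or length offset and the block on SFN and vehicle alone were chosen only after the result was seen; all other settings below were fixed beforehand. In edgeR 0 genes were called in each of the 6 comparisons under DESeq2 size factors, both count filters, the fold minimum of 1.5 and the replicate block, and in each of the 5 comparisons that the fit of the compared groups alone allows. The fold minimum was applied to the calls of the main fit, so its 0 holds by definition. The DESeq2 Wald test called 16 genes in SFN+ZA vs vehicle and 0 elsewhere. Leaving out 1 library in turn gave 0 to 19 genes in SFN+ZA vs vehicle, the 19 without SFN 2, and 0 elsewhere. Without vehicle 2 and SFN 2 the count for SFN+ZA vs vehicle was 52; with the GC offset it was 2, with the GC offset on the compared groups alone 17, with the GC offset and 10 libraries 456, and with a length offset added 401. For SFN+ZA vs ZA the GC offset on the compared groups alone gave 8 and the GC offset with 10 libraries 9; this last setting also gave 2 in SFN vs vehicle, 19 in ZA vs vehicle, 32 in SFN+ZA vs SFN and 2 genes called both for SFN and for ZA. The per-gene spread (biological coefficient of variation) was 0.310 with 12 libraries, 0.125 with 10, 0.183 with the GC offset and 0.0846 with both. With 12 libraries, 757 genes would be expected by chance at an unadjusted edgeR p under 0.05. The numbers were 173 in ZA vs vehicle, 159 in SFN+ZA vs ZA and 257 in the interaction, but 3312 in SFN+ZA vs SFN and 1804 in ZA vs SFN. These p-values departed from a uniform spread in both directions, so 0 calls do not show that no gene changed.

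Lists called with all 12 libraries were 3 in SFN vs vehicle, 2 in ZA vs vehicle, 1 in SFN+ZA vs vehicle and 2 in SFN+ZA vs ZA, and each of these fell to 0 with an estimated correlation. In SFN+ZA vs ZA the estimated correlations of the NRF2 (-0.0090) and interferon (-0.039) lists lay below the preset 0.01. Their unadjusted camera p still rose, from 1.2e-04 to 0.0023 and from 0.0016 to 0.0078. Correlation between the members therefore does not explain the loss of these 2 calls. Without vehicle 2 and SFN 2 the numbers were 1 in ZA vs vehicle, 6 in SFN+ZA vs vehicle and 1 in the interaction. The GC offset gave 4 in ZA vs vehicle, 8 in SFN+ZA vs vehicle and 3 in SFN+ZA vs SFN. The GC offset with 10 libraries gave 9 in SFN+ZA vs vehicle, 1 in SFN+ZA vs SFN, 6 in SFN+ZA vs ZA and 1 in the interaction. The other counts were 3 in SFN vs vehicle and 3 in SFN+ZA vs ZA without the 2 libraries, 4 and 3 with the GC offset, and 4 in SFN vs vehicle and 2 in ZA vs vehicle with both. With an estimated correlation all counts of these 3 settings fell to 0, except 1 in ZA vs vehicle without the 2 libraries and 2 in SFN+ZA vs ZA with the GC offset, without or with the 2 libraries left out. The cause of these shifts was not tested.

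Outside SFN vs vehicle the replicate numbers did not pair the libraries, and within it only number 2 was set apart. Elsewhere residuals of same-numbered libraries correlated from -0.730 to 0.564. Over all 4 groups 9 of 18 pairs were above 0.1 and 5 of 12 libraries correlated best with their own number. With the replicate block on the SFN and vehicle libraries alone, added after seeing the data, 5 lists in place of 3 and, as before, 0 genes passed in SFN vs vehicle; with the GC offset in the same fit the numbers were 4 lists and 0 genes, and none of these lists passed with an estimated correlation. The replicate block over all 12 libraries gave 2 lists in SFN+ZA vs SFN in place of 0, both with adjusted p = 0.74 with an estimated correlation, and C1QL1 turned from -0.15 to 0.40 in SFN+ZA vs vehicle; all other counts of called genes and lists under that block were as without it, so it changed no other call count. No value for the interaction with only the compared groups was possible, since it needs all 4 groups.

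Of 151 pairs of a named gene and a comparison, 2317 values under alternatives were computed, of which 2136 kept the direction and the side of the threshold, 98 newly passed it and 83 had the opposite sign; the cause was not tested. No gene was called by edgeR with all 12 libraries, so none of these values could lose a call. The opposite signs are given as log2 fold changes. Without vehicle 2 and SFN 2 they were those of HMOX1 (-0.10) and HMGCS1 (0.090) in ZA vs vehicle, and GCLM (0.050), TXNRD1 (0.039), HMGCS1 (0.028) and KRT8 (-0.26) in SFN+ZA vs vehicle. The same setting turned TMEM219 (-0.28) in SFN+ZA vs SFN, and NQO1 (-0.024) in the interaction. With the GC offset they were those of HMGCS1 (-0.056) and RHOB (0.18) in SFN vs vehicle, and HMGCS1 (0.015) in ZA vs vehicle. The same setting turned GCLM (0.098), TXNRD1 (0.046), HMGCS1 (0.022) and KRT8 (-0.12) in SFN+ZA vs vehicle, and GCLM (0.024), HMGCS1 (0.078), FDPS (-0.26), RHOB (-0.46) and TMEM219 (-0.17) in SFN+ZA vs SFN. The same setting turned HMGCS1 (0.0063) and FDPS (-0.016) in SFN+ZA vs ZA, and GCLM (0.088), TXNRD1 (0.043), HMGCS1 (0.062) and RHOB (-0.22) in the interaction. With the GC offset and 10 libraries they were those of HMOX1 (-0.12), TXNRD1 (0.011) and HMGCS1 (0.10) in ZA vs vehicle, and GCLM (0.13), TXNRD1 (0.10), HMGCS1 (0.11) and KRT8 (-0.29) in SFN+ZA vs vehicle. The same setting turned GCLM (0.042), TXNRD1 (0.046), HMGCS1 (0.078), RHOB (-0.18) and TMEM219 (-0.43) in SFN+ZA vs SFN, and HMGCS1 (0.0061) and FDPS (-0.014) in SFN+ZA vs ZA. The same setting turned GCLM (0.075) and TXNRD1 (0.035) in the interaction. NQO1 in SFN+ZA vs vehicle was -0.014 with no low-count filter and -0.0012 in the fit of the compared groups alone, against 0.0023 with all 12 libraries.

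Leaving out 1 library in turn gave a sign opposite to that of all 12 for the following, as lowest to highest value. In SFN vs vehicle these were TXNRD1 (-0.026 to 0.30), HMGCS1 (-0.030 to 0.41) and DDX39B (-0.16 to 0.40). In ZA vs vehicle these were HMOX1 (-0.092 to 0.52), HMGCS1 (-0.22 to 0.097) and RHOB (-0.16 to 0.053). In SFN+ZA vs vehicle these were NQO1 (-0.077 to 0.11), GCLM (-0.22 to 0.066), TXNRD1 (-0.15 to 0.055), HMGCS1 (-0.28 to 0.044), RHOB (-0.18 to 0.035), C1QL1 (-0.74 to 0.27), CLIC3 (-0.52 to 0.16), C10orf54 (-0.49 to 0.073) and KRT8 (-0.25 to 0.26). In SFN+ZA vs SFN these were NENF (-0.37 to 0.074), MRPL14 (-0.34 to 0.0073) and TMEM219 (-0.28 to 0.41). In SFN+ZA vs ZA these were HMOX1 (-0.040 to 0.45), HMGCS1 (-0.12 to 0.037), FDPS (-0.091 to 0.082) and RHOB (-0.11 to 0.070). In the interaction these were NQO1 (-0.082 to 0.085) and TXNRD1 (-0.24 to 0.085). Depth limits the precision of low genes, with totals from 15.3 to 25.4 M counts.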

Other observations

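The tests on SFN 2, on vehicle 2 and on the mitochondrial transcripts were chosen only after the result was seen, as were those on the 10 libraries with a GC offset; the length test, the retained-intron test and the other splits of the samples were set before their results were seen.

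Among protein-coding genes called higher in SFN+ZA than in vehicle with the GC offset and 10 libraries, 229 of 299 (76.6%) had an annotated retained-intron transcript, against 57.9% of all protein-coding genes tested. Examples, picked after their values were seen, were OGT (log2 fold change 0.95 ± 0.07 SE, edgeR adjusted p = 2.0e-06), NKTR (0.83 ± 0.08), the splicing helicase gene DDX39B (0.80 ± 0.08) and CCNL2 (0.69 ± 0.08). Adding a length offset left 82.9% of the genes called higher in place, which argues against length bias as their whole cause. A score per library, the mean log2 difference between 7281 genes with and 5285 without such transcripts over 125 bins matched on expression, GC content and length, was 0.0308, 0.0221 and 0.0365 in SFN+ZA 1, 2 and 3 and -0.0177, 0.0118 and -0.0197 in vehicle 1, 2 and 3, a difference of 0.0383. Scores were -0.0081, -0.0488 and -0.0042 in SFN 1, 2 and 3 and -0.0075, 0.0041 and 8.7e-04 in ZA 1, 2 and 3. SFN 2 thus departed from SFN 1 and 3 on a scale like that of the 0.0383. The shares of 76.6% and 57.9% were not matched on expression, GC content or length. The score did not leave out the genes called higher, so it is not independent of these shares. It rests on annotated transcripts, not on intron reads. Its difference of 0.0383 was small beside the 0.69 to 0.95 of the examples. Each SFN+ZA library scored above each vehicle library, as a larger share of intron-retaining or nuclear RNA in SFN+ZA needs. Such a share may contribute as a hypothesis. An exact permutation test of 3 against 3 cannot go below p = 0.1. Counts per gene do not separate this from differences in RNA preparation between groups or from differences between single libraries.

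SFN 2 and vehicle 2 stood apart in their whole profile. Over genes, the SD of the log2 difference from their group mates was 1.37 and 0.770, against at most 0.386 in the other 10 libraries. Once the GC trend was removed it was 0.759 and 0.533, against at most 0.280. SFN 2 and vehicle 2 never served as mates of the others. The trend fitted on GC content of the longest transcript could thus be part of the difference but not all of it. GC effects on fragments or on other transcripts were not tested. Their totals of 18.3 and 17.2 M lay within the 15.3 to 25.4 M of the others, which argues against library size. Summed CPM of blood and immune cell markers was 2.79 in SFN 2, below the 4.32 to 6.01 of the others, and 7.10 in vehicle 2, above them. Only 2 of these markers, and 4 of the fibroblast and endothelial ones, had enough counts to be tested, so RNA from other cells cannot be told apart from chance in few low markers in either library; a mix-up or a difference in RNA handling stays open, and no biological explanation was tested.

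The higher mitochondrial transcripts in SFN+ZA than in vehicle had a median log2 fold change of 1.59 with the GC offset and 1.08 without vehicle 2 and SFN 2, and the shares of 4.69 to 5.30% in SFN+ZA lay above the 3.27% and 1.89% of vehicle 1 and 3. These values argue against the GC trend and against the 2 libraries as the whole cause. The rises in SFN, ZA and SFN+ZA and the negative interaction share the same vehicle libraries, and low shares in vehicle alone could give all of them. SFN+ZA against ZA, a contrast without vehicle, had a list median of 0.14 (camera adjusted p = 0.56). Shares were 4.32, 1.60 and 3.94% in SFN 1, 2 and 3 and 4.76, 4.50 and 4.26% in ZA 1, 2 and 3. RNA preparation and an effect of the treatments remain open and untested. With the correlation between these co-transcribed genes estimated, the camera adjusted p for SFN+ZA against vehicle was 0.25.

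Splits of the 6 libraries of a comparison number 10 with the real one, as do those of the 5 left in SFN+ZA vs vehicle without vehicle 2, so 3 against 3 cannot reach a share under 0.1. The real count of genes with all 12 libraries was 0 in every comparison; the highest other split gave 1 in SFN vs vehicle and 0 in ZA vs vehicle, SFN+ZA vs vehicle, SFN+ZA vs SFN and SFN+ZA vs ZA. With a real count of 0 all 10 of 10 splits give as many by definition, so these counts say nothing of chance. For lists the real count and the highest other were 3 and 5 in SFN vs vehicle (5 of 10 splits gave as many; among the 4 splits that part all 3 numbered pairs the real 3 stood against 3, 0 and 0, and those that part 1 pair gave 2 to 5), 2 and 4 in ZA vs vehicle (5 of 10), 1 and 3 in SFN+ZA vs vehicle (8 of 10), 0 and 7 in SFN+ZA vs SFN (10 of 10, again by definition) and 2 and 1 in SFN+ZA vs ZA (1 of 10). For the interaction all 100 of 100 drawn splits reached the real 0 genes and 0 lists by definition, which says nothing of chance either. The highest interaction split gave 2248 genes and 8 lists, which points to a structure of the samples that the treatment groups do not describe. On 10 libraries with the GC offset, 456 genes in SFN+ZA vs vehicle stood against at most 1 in other splits and 9 lists against 7. For SFN+ZA vs ZA 9 genes stood against 0 and 6 lists against 2, and the real split was the only 1 as large in each of these 4 cases.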
